A study of Mus musculus with 4 samples.

How the data were processed

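The study profiled a mouse pre-B acute lymphoblastic leukemia (ALL) culture by chromatin immunoprecipitation and sequencing (ChIP-seq), in which crosslinked, sheared chromatin is captured with an antibody and the recovered DNA is sequenced. Per the labels, the cells were C57BL/6J pre-B leukemia cells transformed with the BCR-ABL1 fusion kinase on a p19 null background. The series held 4 libraries: a PHF6 ChIP, an H3K27ac ChIP, an H3K27me3 ChIP and an input DNA library without antibody. Each antibody had 1 library, so groups were single samples and no difference had a replicate check.

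The labels' protocols describe formaldehyde crosslinking, sonication of isolated nuclei, size-selected Illumina libraries and single-read sequencing. Bowtie2, SAMtools and MACS 1.4.0 are named with mouse build mm9 in the submitters' processing notes, without their order or options. The names of the deposited lists gave a threshold of 1e-6 for all 3 lists. They marked the PHF6 and H3K27ac lists, but not the H3K27me3 list, as made without the peak caller's local background (lambda), so the lists were not called under 1 setting. Whether the input library served as control is not given in the sources used here.

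Each ChIP library came with a peak list and a summit list. The score deposited with each peak had a smallest value of 60, which is 10 times the negative log10 of the threshold. It reached a ceiling near 3100 in 8251 of the 32388 H3K27ac peaks, 15 PHF6 peaks and 31 H3K27me3 peaks, so it did not rank the strongest H3K27ac peaks. The signal deposited with each summit was a whole-number pileup height, here called summit height. Its largest value was 400 in each of the 3 lists, so it may have an upper limit, which was not tested. Score and height are the authors' own values per peak and were used only to rank, describe or filter peaks within 1 list. The lists give no read totals, so sequencing depth is unknown and heights were not compared between antibodies. No list was described as pooled.

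All summits lay inside their peaks, no peaks of 1 list overlapped each other, and no peak lay outside the assembled mm9 chromosomes. No peak passed the end of an mm9 chromosome, while 9 chromosomes of the PHF6 list held peaks past the end of the mm10 chromosome. The gene table at hand belongs to GRCm38, so gene positions and genome sequence were not used here. Shares of peaks at transcription start sites, promoter states of genes, the gene lists fixed in advance and consensus sequences at summits were therefore not analysed here, and peaks are given by mm9 position and cytogenetic band. Bands were taken from circlize 0.4.16 and chromosome lengths from GenomeInfoDb 1.38.1, under R 4.3.3. All other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

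Peaks were called overlapping when they shared at least 1 bp. The observed share was set beside 100 random placements in which all peaks of a chromosome were shifted together by 1 random distance, wrapping around its end. A second set of 100 placements, chosen after seeing the data, moved each peak by 50 to 500 kb to either side, which keeps it in its own neighbourhood. For peaks split by a second mark, moved peaks entered the expected value only where they landed in the same class. Shares carry 95% exact (Clopper-Pearson) binomial intervals. These intervals cover counting error only, neighbouring peaks are not independent, and no p-value was computed because each antibody had 1 library. H3K27ac peaks were joined at gaps of up to 12.5 kb and ranked by the peak bases they cover. H3K27me3 peaks were joined at gaps of up to 5 kb and ranked likewise. Ranks by summit height were cut into deciles, ties in file order. The text gives, by a rule set in advance, the 10 tallest summits of each list and the 10 top-ranked joined regions of each histone mark, printed in full for PHF6 summits and in part for the others.

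The overlap routine was tested on simulated lists with the real peak widths, placed at uniform random positions on each chromosome. They lack the clustering of the real lists, so the test checks the routine and not the expected shares for clustered lists. With no planted overlap, 74344 simulated PHF6 peaks gave a ratio of observed to expected of 0.974 on H3K27ac, and 5600 simulated H3K27me3 peaks gave 0.989 on PHF6. With 30% of PHF6 peaks planted on H3K27ac the routine returned 34.2%, the planted peaks plus chance overlap, against 4.17% expected. The alternatives were other overlap rules, a score of at least 100, equal list sizes, leaving out regions present in all 3 lists, other placements, other rankings and other joining gaps.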

Results

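Binding of PHF6, a chromatin-associated protein with PHD-type zinc fingers, was mapped in BCR-ABL1 transformed mouse pre-B ALL cells together with 2 modifications of lysine 27 of histone H3. Acetylation (H3K27ac) marks active promoters and enhancers, and trimethylation (H3K27me3) is deposited by Polycomb repressive complex 2. The PHF6 list held 77749 peaks with a median width of 1065 bp, which together covered 103 Mb or 3.87% of the mm9 assembly. The H3K27ac list held 32388 peaks with a median width of 1484 bp, covering 58.3 Mb or 2.19%. The H3K27me3 list held 5616 peaks with a median width of 943 bp, covering 6.29 Mb or 0.237%. Each list came from 1 library, so the values describe these libraries and have no replicate error. The number of reads behind each list is unknown and the H3K27me3 list was called under another setting, so peak counts cannot be compared between antibodies and shares depend on list length. Median summit heights were 22 (quartiles 19 and 27) for PHF6, 35 (20 and 173) for H3K27ac and 16 (13 and 22) for H3K27me3.

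The first comparison asked how PHF6 lies relative to H3K27 acetylation. PHF6 and H3K27ac coincided: 23523 of 77749 PHF6 peaks (30.3%, 95% interval 29.9 to 30.6) overlapped an H3K27ac peak. Seen from the histone mark, 23213 of 32388 H3K27ac peaks (71.7%, 71.2 to 72.2) held PHF6. With each list cut to its 5616 highest-scoring peaks, these shares were 22.4% and 22.2%. That cut lies within the 8251 H3K27ac peaks at the score ceiling, where ties were broken by height. It also leaves out most PHF6 peaks, so it does not give the share of strong H3K27ac peaks that held any PHF6 peak. Circular shifts gave 4.22% (range 3.57 to 5.24) for PHF6 peaks on H3K27ac and 9.24% (7.74 to 11.4) for H3K27ac peaks on PHF6, so the observed shares were 7.17 and 7.76 times those expected. Both lists are dense in the same parts of the genome, and moves of 50 to 500 kb gave higher expected shares of 10.2% (9.98 to 10.4) and 21.9% (21.5 to 22.4). Against these local placements the ratios were 2.96 and 3.28. Summits of PHF6 peaks that overlapped H3K27ac lay a median of 108 bp (quartiles 38 and 342) from the nearest H3K27ac summit of any peak. Of these PHF6 summits, 48.1% (47.4 to 48.7) were within 100 bp of an H3K27ac summit, against 12.8% for random positions in the same PHF6 peaks. The input library was not analysed here. Signal common to both libraries was therefore not tested as a source of this overlap or of the height comparisons below.

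**Figure D1:**
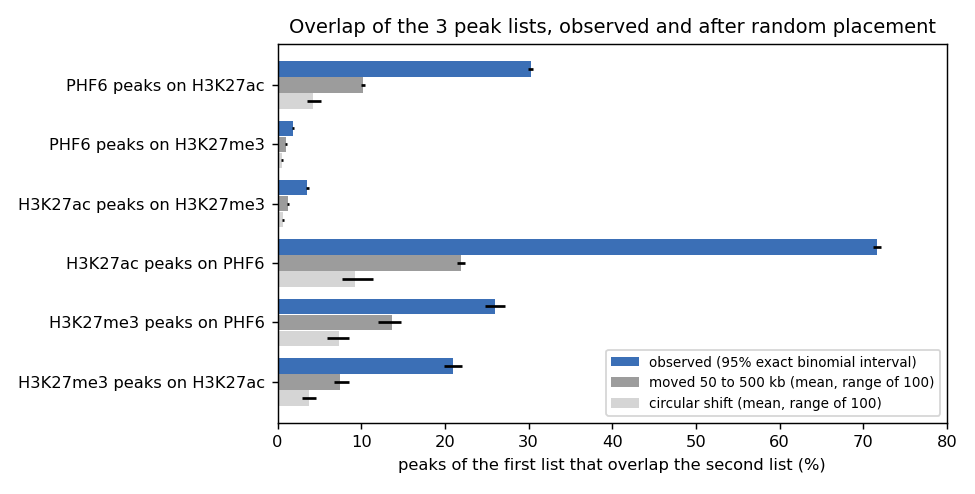
Bars show the share of peaks of the first list (%, x axis) that overlap a peak of the second list, as observed with 95% exact binomial intervals and as the mean and range over 100 random placements of 2 kinds. The 71.7% of H3K27ac peaks that held PHF6 stand against 21.9% after local moves and 9.24% after circular shifts.

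Taller PHF6 peaks were more often acetylated. PHF6 peaks with H3K27ac had a median summit height of 29 (quartiles 24 and 36, n = 23523 peaks) and those without had 20 (18 and 23, n = 54226 peaks). A PHF6 peak with H3K27ac outranked one without in 85.0% of pairs, with tied pairs split evenly. In the lowest decile of PHF6 peaks by height, 4.82% (4.36 to 5.32) overlapped H3K27ac, less than the 7.47% that local moves of the same peaks gave. The fifth decile stood at 16.0% (15.2 to 16.8), the ninth at 68.4% (67.4 to 69.4) and the top decile at 93.1% (92.5 to 93.6). Local moves of the top decile, which keep its wider peaks, gave 13.6%. The remaining 54226 PHF6 peaks without H3K27ac lay a median of 17.8 kb (quartiles 6.38 and 55.6) from the nearest H3K27ac summit.

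Among H3K27ac peaks, PHF6 was most frequent at both ends of the height ranking. The top decile, with heights of 311 to 400, held PHF6 in 98.6% (98.1 to 99.0) of peaks, and the ninth decile in 94.6% (93.8 to 95.4). The share fell to 45.6% (43.9 to 47.3) in the sixth decile, with heights of 35 to 56. It was 80.6% (79.2 to 82.0) in the lowest decile, with heights of 11 to 16. Local moves of the same peaks gave 16.3% in the lowest, 20.9% in the sixth and 25.4% in the top decile.

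**Figure D2:**
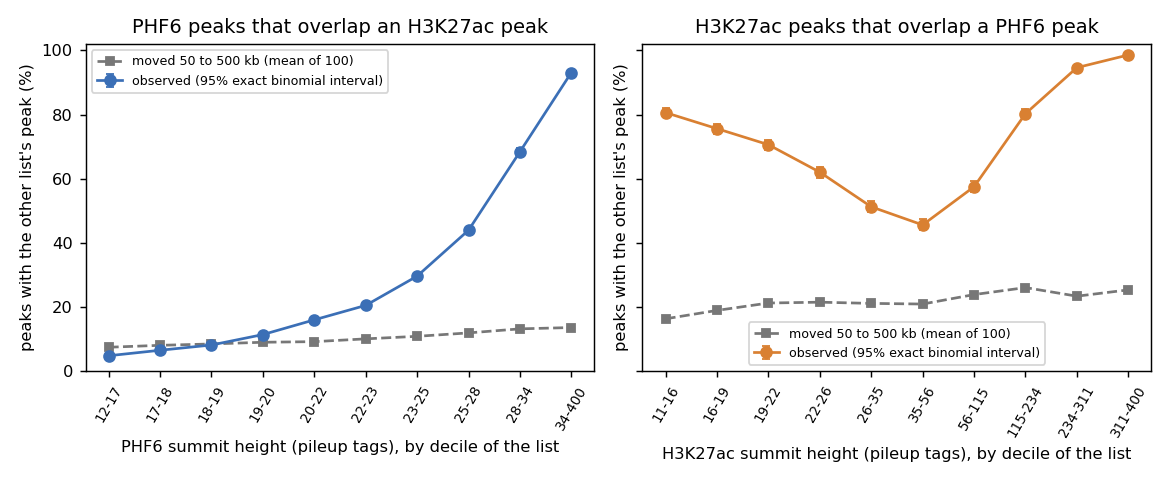
The y axis gives the share of peaks (%) with a peak of the other list, and the x axis the summit height range (pileup tags) of each decile of the list, for PHF6 peaks on the left and H3K27ac peaks on the right. Circles are observed shares with 95% exact binomial intervals and squares the mean of 100 local moves; the left curve climbs from 4.82% to 93.1%, and the right one dips to 45.6% in the sixth decile.

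The second comparison asked how PHF6 lies relative to H3K27 trimethylation. Few PHF6 peaks overlapped the H3K27me3 list, the shortest of the 3. Of 77749 PHF6 peaks, 1462 (1.88%, 1.79 to 1.98) overlapped an H3K27me3 peak, and 1458 of 5616 H3K27me3 peaks (26.0%, 24.8 to 27.1) held PHF6. With 5616 peaks in each list the shares were 8.60% and 9.33%. Circular shifts gave 0.548% and 7.31%, for ratios of 3.43 and 3.55, and local moves gave 1.02% and 13.6%, for ratios of 1.84 and 1.90. With regions present in all 3 lists left out, which removes overlapping peaks by construction, the ratio over circular shifts was 1.46 for PHF6 peaks on H3K27me3 and 1.47 for H3K27me3 peaks on PHF6.

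Splitting the H3K27me3 peaks by acetylation separated these sites. Of 1180 H3K27me3 peaks that overlapped H3K27ac, 931 (78.9%, 76.5 to 81.2) held PHF6. Of 4436 H3K27me3 peaks without H3K27ac, 527 (11.9%, 10.9 to 12.9) did. Without the top decile by height of each list, a run added after seeing the data, the shares were 52.4% (49.0 to 55.7) of 890 peaks and 11.2% of 4176 peaks. That run also drops the tallest PHF6 peaks, which lowers the share by construction. With all PHF6 peaks kept, and H3K27me3 peaks left out when in the top decile or on a top-decile H3K27ac peak, the shares were 81.1% (78.3 to 83.6) of 888 peaks and 11.7% of 4075 peaks. Random placements that landed on H3K27ac met PHF6 in 66.3% of cases under circular shifts (highest of 100, 76.1%) and in 70.8% under local moves (highest 75.5%), so these peaks held PHF6 1.19 and 1.11 times as often as other acetylated positions. For peaks without H3K27ac, placements that missed H3K27ac met PHF6 in 4.98% (highest 6.08%) and 9.04% (highest 10.2%) of cases, for ratios of 2.38 and 1.31. H3K27me3 and PHF6 summits were farther apart than H3K27ac and PHF6 summits. Summits of PHF6 peaks that overlapped H3K27me3 lay a median of 430 bp (quartiles 128 and 947) from the nearest H3K27me3 summit of any peak. Of these PHF6 summits, 20.2% (18.2 to 22.4) were within 100 bp of an H3K27me3 summit, against 9.03% for random positions.

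The 2 histone marks were also compared with each other. H3K27me3 overlapped 1158 of 32388 H3K27ac peaks (3.58%, 3.38 to 3.78), against 0.637% (range 0.513 to 0.803) under circular shifts and 1.23% (1.1 to 1.4) under local moves. From the other side, 1180 of 5616 H3K27me3 peaks (21.0%, 19.95 to 22.10) overlapped H3K27ac, against 3.79% and 7.43%. Leaving out regions in all 3 lists brought the first share to 0.506%, against 0.506% under circular shifts, but this removes 996 of the 1158 overlapping peaks because they overlap. In a split by PHF6, added after seeing the data, H3K27me3 was at 4.29% (4.03 to 4.56) of H3K27ac peaks with PHF6, and same-class placements gave 2.38% under circular shifts and 2.72% under local moves. Without PHF6 it was at 1.77% (1.51 to 2.06), against 0.460% and 0.817%. H3K27ac peaks with H3K27me3 held PHF6 in 86.0% (83.9 to 88.0) of cases and those without in 71.1% (70.6 to 71.6). Placements landing in the same class gave 34.4% and 9.07% under circular shifts, for ratios of 2.5 and 7.84, and 48.2% and 21.5% under local moves, for ratios of 1.78 and 3.30. The peaks with H3K27me3 had the higher share and the lower ratio to placement. Lists of regions do not show whether 2 marks sit on the same nucleosome or in the same cell.

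Put together per peak, 53718 PHF6 peaks (69.1%, 68.8 to 69.4) overlapped no called peak of either mark and had a median height of 20. H3K27ac alone was present at 22569 PHF6 peaks (29.0%, 28.7 to 29.3), with a median height of 29. Both marks were present at 954 (1.23%, 1.15 to 1.31), with a median height of 33. H3K27me3 alone was present at 508 (0.653%, 0.598 to 0.713), with a median height of 22.

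The tallest summits of the 3 lists partly coincided. All 10 of the tallest PHF6 summits lay in H3K27ac peaks, and 4 of them were also in H3K27me3 peaks. These 4 were on chromosome 2 at 98505935 to 98507820 (band qE1, PHF6 height 400) and at 98502119 to 98504733 (qE1, 372), on chromosome 17 at 39979688 to 39986128 (qB1, 399) and on chromosome 9 at 35112356 to 35113463 (qA4, 387). Their PHF6 scores were 229 and 298 for the 2 sites on chromosome 2, 3100 on chromosome 17 and 520 on chromosome 9, so height and score ranked them differently. They also held 4 of the 10 tallest H3K27me3 summits and, on chromosomes 2 and 17, the 2 tallest H3K27ac summits. At the first chromosome 2 site the 3 summits had height 400, at 98506948 (PHF6), 98506944 (H3K27ac) and 98506945 (H3K27me3). A height of 400 was the largest in each list, so the equal heights may reflect an upper limit and need not mean equal signal. Of the 10 tallest H3K27me3 summits, 7 were in all 3 lists and 9 in H3K27ac peaks, against 16.6% and 21.0% of the list. Signal common to all 3 libraries was not tested at these sites, since the input library was not analysed here. Tall PHF6 peaks with H3K27ac and without H3K27me3 were found on chromosome 16 at 11143474 to 11144852 (qA1, height 377), chromosome 17 at 85488987 to 85490942 (qE4, 371), chromosome 2 at 72313512 to 72315508 (qC3, 359) and chromosome 17 at 13742989 to 13746499 (qA1, 344). The last 2 of the 10 were chromosome 11 at 108872463 to 108873948 (qE1, 343) and chromosome 4 at 118219311 to 118221797 (qD2.1, 332). Of the 10 tallest H3K27ac summits, 8 held PHF6. The exceptions were on chromosome 8 at 19783697 to 19786081 (qA1.3, H3K27ac height 388) and on chromosome 1 at 90170639 to 90175440 (qD, 388).

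Joining H3K27ac peaks gave 17585 regions, of which the 500 that covered the most bases held 5709 H3K27ac peaks. PHF6 was present in 486 of these 500 (97.2%, 95.3 to 98.5) and in 12702 of the 17085 others (74.3%, 73.7 to 75). The top regions held a median of 10 H3K27ac peaks and the others a median of 1. Larger regions have more room to hold a PHF6 peak, and no expectation for region size was computed. The shares therefore do not show that PHF6 favoured the top regions. PHF6 summits anywhere in a region, gaps included, numbered 0.508 and 0.471 per kb of H3K27ac peak in the 2 classes. Gaps add summits but no H3K27ac bases, and 12133 of the other regions were single peaks without gaps. These values are therefore not densities within H3K27ac peaks. The top-ranked region spanned chromosome 10 from 79312325 to 79660557 (qC1) and held 72 H3K27ac peaks over 194 kb, 93 PHF6 peaks and 10 H3K27me3 peaks. The second lay on chromosome 8 from 73085773 to 73439100 (qB3.3), with 70 H3K27ac and 83 PHF6 peaks. Another 3 of the first 5 were in the same band of chromosome 10, between 79703399 and 80897737. The seventh, on chromosome 19 from 4096420 to 4233715 (qA), had the tallest H3K27ac peaks of the 10, with a median height of 158 over 26 peaks, and held 31 PHF6 peaks.

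As called in this list, H3K27me3 peaks were mostly isolated: joining them gave 4551 regions, and 3910 of these were single peaks. Trimethylated domains can be broader than the peak caller's default, so wide domains may have been split or missed, which was not tested. The top-ranked region covered 77.3 kb with 31 H3K27me3 peaks on chromosome 8 from 126062249 to 126148120 (qE2). It held 8 H3K27ac peaks and 0 PHF6 peaks, while the flanks of equal length held 19 and 13 PHF6 peaks. The second covered 34.2 kb with 19 H3K27me3 peaks on chromosome 15 from 102771115 to 102828151 (qF3) and held 10 H3K27ac and 10 PHF6 peaks. Among the 10 top-ranked regions, 4 held 0 PHF6 peaks, the others being on chromosome 14 at 27459729 to 27478527 (qA3), chromosome 3 at 106012718 to 106031222 (qF2.2) and chromosome X at 122692992 to 122713640 (qE3). Over the 100 top-ranked regions, 145 PHF6 summits lay inside (124 per Mb) and 245 in the flanks of equal length on both sides (105 per Mb). The ratio of these densities was 1.18 with a 95% counting interval of 0.957 to 1.46, so no difference was detectable in these regions. Over the 500 top-ranked regions, which include shorter ones, there were 404 summits inside (132 per Mb) and 575 in the flanks (94.2 per Mb), a ratio of 1.41 (1.23 to 1.6). H3K27ac summits were also denser inside, at 66.7 against 47.9 per Mb for the top 100 (ratio 1.39, 1.03 to 1.88) and 84.8 against 53.6 per Mb for the top 500 (1.58, 1.34 to 1.87).

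**Figure D3:**
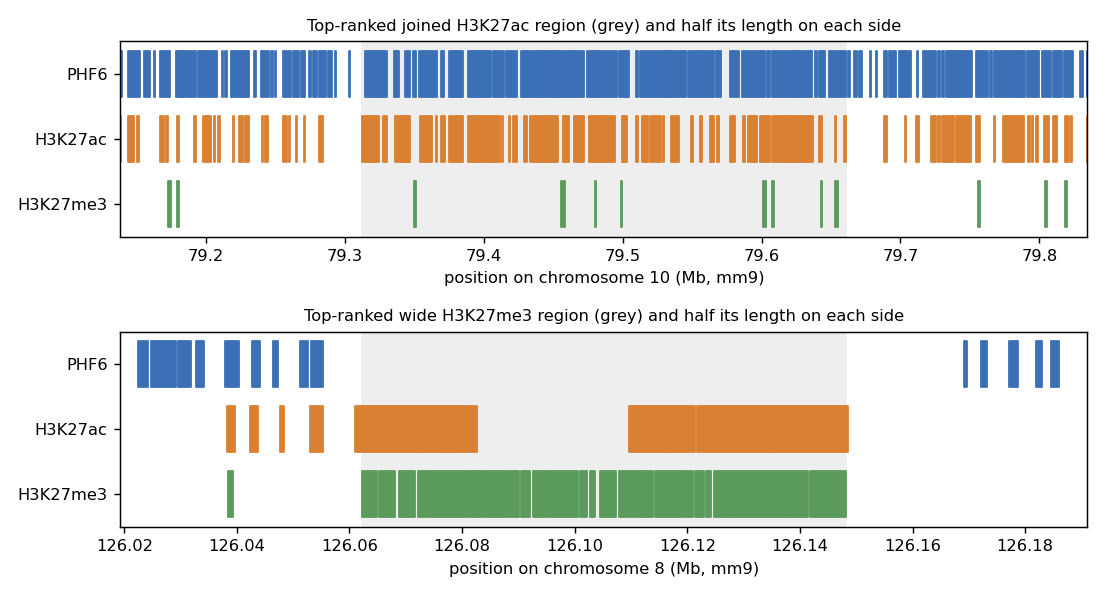
Blocks mark the peaks of each list along the top-ranked joined H3K27ac region of chromosome 10 (upper map) and the top-ranked H3K27me3 region of chromosome 8 (lower map), in Mb of mm9, to scale, with the region in grey. The upper region holds 93 PHF6 and 72 H3K27ac peaks; the lower one holds 31 H3K27me3 and 8 H3K27ac peaks and 0 PHF6 peaks.

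Peaks of all 3 antibodies were unevenly spread over the chromosomes. PHF6 was densest on chromosome 11 (52.6 peaks per Mb) and sparsest among autosomes on chromosome 3 (16.7), and the H3K27ac list had the same extremes (22.2 and 8.44). H3K27me3 ranged from 3.98 per Mb on chromosome 11 to 1.33 on chromosome 18. Chromosome X held 6.17 PHF6 peaks per Mb against 31.0 on the autosomes, a ratio of 0.199 (95% counting interval 0.187 to 0.211). The same ratio was 0.305 (0.282 to 0.329) for H3K27ac and 0.544 (0.470 to 0.628) for H3K27me3. Light cytogenetic bands, which are gene-rich, make up 41.2% of the autosomes and held 52.6% of PHF6, 49.9% of H3K27ac and 46.8% of H3K27me3 peaks. The darkest bands make up 31.2% and held 18.2%, 19.5% and 21.8%. On each autosome between 27.6% and 35.7% of PHF6 peaks overlapped H3K27ac, and between 60.03% and 79.5% of H3K27ac peaks held PHF6.

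**Figure D4:**
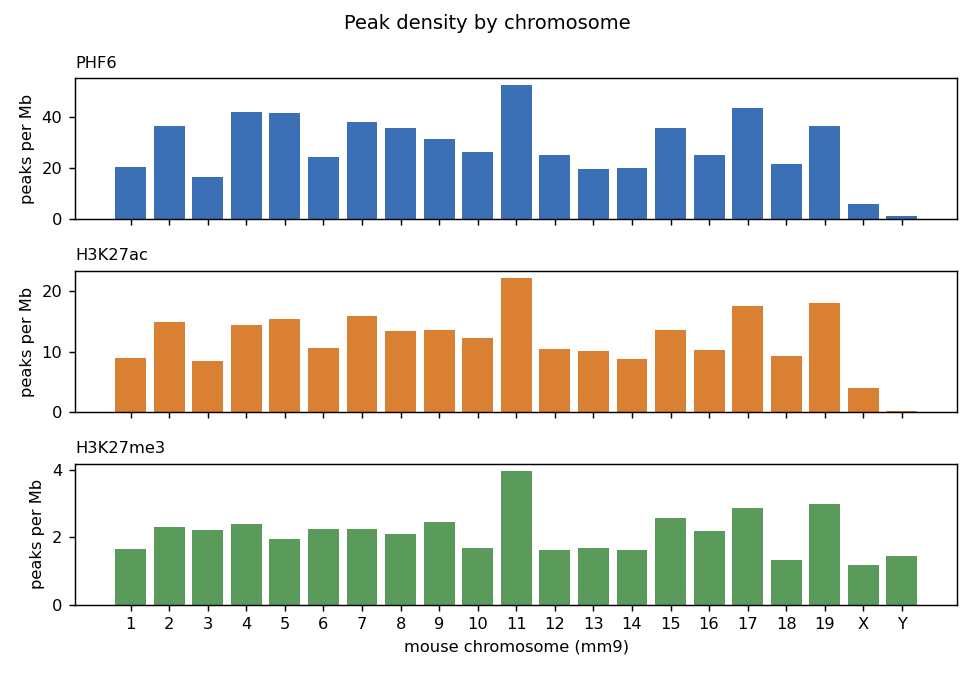
Bars give the number of peaks per Mb (y axis) on each mouse chromosome (x axis, mm9) for PHF6, H3K27ac and H3K27me3. Chromosome 11 is the densest in each list, and chromosome X falls below every autosome, with 6.17 PHF6 peaks per Mb.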

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

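Alternatives were fixed before the data were examined, except local placement, shifts over the span of peaks and runs without chromosomes X and Y. Runs on peaks split by another list were also added later, apart from those on PHF6 heights, which were fixed in advance. In none of the alternatives did a ratio of observed to expected overlap fall below 1. For PHF6 peaks on H3K27ac (7.17) the ratio was 10.4 when 50% of the shorter peak had to overlap, 11.4 with the summit inside the other peak, 8.77 at a score of at least 100, 15.8 with 5616 peaks per list, 7.26 with independent placement and 2.96 with local placement. For H3K27ac peaks on PHF6 (7.76) it was 10.9, 15.7, 9.30, 16.0, 7.84 and 3.28 under the same settings, and 7.68 with shifts over the span of peaks. For PHF6 peaks on H3K27me3 (3.43) it was 4.32, 4.71, 4.69 and 9.12 under the first 4, 1.84 with local placement and 1.46 without regions in all 3 lists. For H3K27me3 peaks on PHF6 (3.55) these were 4.42, 4.76, 4.82, 9.08, 1.90 and 1.47. For H3K27ac peaks on H3K27me3 (5.61) they were 6.71, 8.68, 7.21, 4.48, 2.90 and 1.0. Leaving out regions in all 3 lists removes overlapping peaks by construction. With equal list sizes, ties at the score ceiling were broken by height. The share of H3K27me3 peaks with H3K27ac that held PHF6 (78.9%) was 74.5% at a score of at least 100 and 52.4% without the top decile by height of each list, 81.1% with all PHF6 peaks kept and only tall sites of the 2 marks left out, and the share of those without H3K27ac (11.9%) was 9.66% with that 50% rule. The share of pairs in which the acetylated PHF6 peak ranked higher, with ties split evenly (85.0%), was 85.7% at a score of at least 100 and 79.7% by score in place of height. PHF6 was in 99.8% of the top 500 joined H3K27ac regions when ranked by summed height and in 94.8% with a gap of 5 kb. Another 19 settings stayed within the counting interval or, for the 4551 joined H3K27me3 regions, within 1.5 times the count. Alternatives that need gene positions or sequence were not run. No paired analysis was possible because each antibody had 1 library. Read totals are unknown, so what depth limits in each list could not be measured.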

Other observations

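The tests of local PHF6 density, of tall sites with all PHF6 peaks kept and of chromosome X against H3K27ac density were chosen after the result was seen, as was the use of median and matched heights on X, without which the top-decile share there would have counted for lower depth. No biological contrast was part of the design.

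The top-ranked H3K27me3 region of chromosome 8 had a further feature, singled out after its values were seen. Its 8 H3K27ac peaks covered 58.3 kb, of which 53.6 kb were also inside H3K27me3 peaks. The outermost H3K27ac and H3K27me3 edges differed by 471 bp on the right and 1212 bp on the left. H3K27ac heights there ran from 28 to 46 and H3K27me3 heights from 13 to 23. The nearest PHF6 peaks were 6.96 kb to the left and 21.0 kb to the right. Another dense stretch lay on chromosome 6 from 114444964 to 114595596 (qE3). It held 58 H3K27ac peaks with a median height of 20 and 60 PHF6 peaks with a median height of 31, with 0 H3K27me3 peaks, while its flanks held 1 and 3 H3K27ac peaks and 10 and 6 PHF6 peaks.

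PHF6 was at 80.6% of the lowest decile of H3K27ac peaks and 45.6% of the sixth. A denser PHF6 neighbourhood at 50 to 500 kb was argued against as the whole cause. Summit windows of 1 kb, which leave peak width out, held PHF6 in 80.8% and 43.7% of cases (ratio 1.85). After moves of 50 to 500 kb the shares were 16.5% and 16.9% (highest ratio of 100 placements, 1.09). PHF6 density within 50 kb was not sampled. One hypothesis is that the lowest-decile peaks are PHF6 sites with little acetylation. With PHF6 peaks of score at least 100 the shares were 75.8% and 36.1%, so the contrast did not rest on the weakest PHF6 peaks. Signal common to both libraries, such as fragments recovered without regard to the antibody, may give the same contrast. The tallest PHF6 peak over each H3K27ac peak of the lowest decile had a median height of 25. That lay between the median (22) and the upper quartile (27) of the PHF6 list, although taking the tallest can raise it. It was also the lowest median of the 10 deciles, against 27 in the sixth and 42 in the top one. Signal common to both libraries therefore cannot be told apart without a list from the input library, which was not analysed here.

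The second pattern is that PHF6 was at 78.9% of H3K27me3 peaks with H3K27ac and at 11.9% of those without. Regions of very high signal in every library were argued against as the whole cause, since without the top decile by height of each list the shares were 52.4% (49.0 to 55.7) and 11.2%. That run drops tall PHF6 peaks and so lowers the share by construction, and with all PHF6 peaks kept and tall sites of the 2 marks left out the shares were 81.1% (78.3 to 83.6) and 11.7%. After moves of 50 to 500 kb the acetylated H3K27me3 peaks met PHF6 in 22.7% of cases (highest of 100 placements, 24.8%), wherever they landed. That was below the bound set in advance for crowding of peaks. The moves need not land on acetylated sites and skip the nearest 50 kb, so they cannot decide on crowding at acetylated sites. Placements that landed on H3K27ac met PHF6 in 66.3% under circular shifts and 70.8% under local moves, so most of the contrast goes with acetylated positions in general (ratios of 1.19 and 1.11), and a mixture of cell states or capture common to all antibodies stays open and untested.

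The third pattern is the low PHF6 density on chromosome X. Fewer acetylated sites alone were argued against as the whole cause, since the X to autosome ratio was 0.199 for PHF6 and 0.305 for H3K27ac. Lower read depth on X may contribute but cannot be told apart. As lower depth would give, 3.07% (1.88 to 4.70) of H3K27ac peaks on X were in the top decile against 10.1% on autosomes. The seventh to ninth deciles held 13.2%, 20.4% and 12.6% of the X peaks and the lowest 13.8%. Median heights on X and autosomes were 53 and 35 for H3K27ac, 21 and 16 for H3K27me3 and 20 and 22 for PHF6. Lower depth can also take weak peaks below the threshold, so a higher median on X does not argue against it. At matched H3K27ac height the observed PHF6 share was lower on X in every decile. In the fourth decile it was 17.0% (8.07 to 29.8) of X peaks against 62.8% on autosomes. The fifth gave 7.69% (1.62 to 20.9) against 51.8% and the seventh 20.9% (12.9 to 31.0) against 58.5%. In the second decile and the top 2 deciles the X interval included the autosomal share. There the shares were 70% (53.5 to 83.4) against 75.7%, 89.0% (80.2 to 94.9) against 94.8% and 95% (75.1 to 99.9) against 98.6%. Equal H3K27ac height need not mean equal PHF6 depth, so lower PHF6 occupancy of X sites of intermediate acetylation also stays open.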
